A study of Drosophila melanogaster with 3 samples.

How the data were processed

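ChIP-seq was performed on whole embryos of 0 to 16 h from a transgenic Drosophila line expressing CG16863 with a C-terminal eGFP tag, with an antibody against GFP, per the labels' protocols. Chromatin was sonicated and fragments of 200 to 800 bp were selected, per the labels. The 3 samples are biological replicates of 1 group and were numbered as the labels number them. All are samples of the same line, and no contrast between groups was made. A control library file was not used here, so signal that does not come from the tagged protein could not be told apart from its binding.

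The deposited files are peak lists made by the authors on the dm6 and dm3 genome builds, per the labels. For each build there is a relaxed list per replicate, a relaxed list of the pooled replicates and an IDR set. The aligner, the peak caller, the IDR settings and the read depth are not given in the sources used here. The peak height is a signal value that the authors deposited for each peak, and values of the replicate lists were compared only after division by the median of each replicate. The IDR set and the pooled list hold the same signal values for the peaks they share, so these lists were compared directly. The significance in the deposited lists is a −log10 q value, which was used only to describe the lists. In both builds every peak of the IDR set was found in the pooled list, and the IDR set was exactly the pooled peaks at or above a single signal value (108.6 in dm6). The dm6 IDR set therefore equals the top 16.8% of the 23571 pooled peaks, and 3859 of 21109 pooled peaks make up the dm3 set. The median peak width of the dm6 IDR set was 430 bp. Because pooled signal decides this set, leaving out a replicate could not be done on the IDR set itself, and the peaks shared by the other replicates within 100 bp among their 3953 strongest were used (2766 to 2854 peaks).

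Coordinates are 1-based dm6 coordinates, and dm3 lists were used only for counts, shares and the comparison of replicates, within that build. Genes, transcripts and features came from Ensembl release 115 (BDGP6.54, the same coordinates as dm6), with 18164 genes on the 6 arms used, transposable elements left out. A summit within 500 bp of any annotated TSS was called promoter. Other summits took the first of 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic that applied. The background for peaks was all pooled relaxed summits over 1000 bp from every IDR summit (17875), and for genes all 7578 with a pooled relaxed summit within 500 bp of a TSS. These are sites called with relaxed settings, and results are conditional on having a relaxed peak. Of the 23571 pooled peaks, 4878 had a q value of at most 0.01, all 3953 IDR peaks among them. Most background summits were therefore weak calls, and the comparisons set strong peaks against mostly weak ones. The signal of a replicate at a reproducible peak was that of its highest relaxed peak with a summit within 100 bp. It was divided by the median of the replicate, and summits without such a peak (103 to 147 per replicate) were ranked lowest.

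Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 7 feature classes, 6 arms, 34 gene lists, 30 motifs and 10 held-out 8-mers, each as its own family, at a threshold of 0.05. Intervals are 95% Wilson intervals and cover counting error only. Peaks and genes are not independent replicates, so these p-values describe the lists and not the spread between embryos. The spread between replicates is given as SD over 3 replicates or 3 pairs. The overlap of the strongest peaks was compared with 1000 random circular shifts of one list along each arm. For motifs and 8-mers, windows of 101 bp around the summits were matched 1 to 1 with background windows on promoter class and 5% GC bins. An 8-mer was ranked when at least 10 windows held it. The peaks named in the text are the 25 reproducible peaks with the best mean rank of signal over the replicates, each named by the gene with the nearest TSS. CG16863 itself was added, as were up to 4 bound members with the best mean rank in each list past the threshold and up to 2 in other lists described. The gene lists, the motifs, this rule, the tests of the main comparisons and most alternatives were fixed before the data were examined. Some tests of explanations in the closing section were chosen later, as stated there.

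The tests were checked on simulated data. With windows drawn at random from the background in a single run, 0 of 30 motifs and 0 of 10 8-mers were called. A planted 8-mer was recovered when it was in 1, 2 and 5% of windows, in a single run of each. These runs did not use the matching on promoter class and GC. With the odds of being bound raised 4 times, cytosolic ribosomal proteins were called in 50 of 50 simulations, oxidative phosphorylation in 47, cell cycle in 39 and Hox in 4, so small lists had little power. Of 1450 tests on lists left unchanged, 9 gave a call. The alternatives tried were other TSS windows, summit distances, backgrounds, peak sets, gene definitions, the dm3 lists, and leaving out each replicate. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.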

Results

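Binding of the protein encoded by CG16863 was mapped by ChIP-seq in whole Drosophila melanogaster embryos. The embryos were 0 to 16 h old, of mixed sex, and from a transgenic line that expresses CG16863 fused to eGFP, a green fluorescent protein used here as the tag for immunoprecipitation. The series holds 3 biological replicates of this single group, so the design implies no contrast between groups. It asks instead where the tagged protein was bound, how well the replicates matched, and which genes, features and sequences lay at the bound sites. The authors deposited relaxed peak lists for each replicate and for the pooled replicates, and a set of reproducible peaks chosen by irreproducible discovery rate (IDR) analysis. On the dm6 genome build the relaxed lists held 24378 peaks in replicate 1, 30000 in replicate 2, 29769 in replicate 3 and 23571 in the pooled replicates. The IDR set held 3953 peaks, which are called reproducible peaks below. Read depth is not known from these files, so no counting error can be given for the height of a peak. Peak heights are the authors' signal values. They were divided by the median of each replicate over the reproducible peaks and are given as relative signal, mean ± SD over replicates.

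The strongest binding was at the promoter of zip, which encodes the heavy chain of non-muscle myosin II (FBgn0287873). This peak covered 2R 25011252 to 25012132 in dm6, its summit lay 82 bp upstream of a zip transcription start site (TSS), and its relative signal was 36.4 ± 2.98 (SD, n = 3). The second-ranked peak lay 30 bp upstream of kermit (FBgn0010504) at 2R 8156311 to 8156961, with a relative signal of 27.7 ± 4.58 (SD, n = 3). Start sites of Lpin and lncRNA:CR44068 were also within 500 bp of its summit. Next were EDTP (19.2 ± 1.23), a phosphatase first described from eggs, Manf (19.6 ± 3.24), the homologue of a secreted neurotrophic factor, and the tyrosine phosphatase gene Ptpmeg2 (17.8 ± 1.69; SD, n = 3 for each). The EDTP peak lay at 2R 17444813 to 17445281 and the Manf peak at 3R 16349102 to 16349657. The Manf summit was also within 500 bp of a TSS of CG14879. Relative signals of these peaks overlapped within their replicate spread from EDTP to Ptpmeg2, whereas zip exceeded every one of them in each replicate.

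Of the 25 reproducible peaks with the best mean rank over the replicates, 20 lay within 500 bp of a TSS, 3 in introns and 2 between genes. Their relative signals ran from 8.46 to 36.4. The promoter peaks included genes for chromatin proteins. The peak at ph-p (X 2137172 to 2137577), a Polycomb group gene, had a relative signal of 11.7 ± 1.02 (SD, n = 3) and its summit was 492 bp from the TSS. The peak at Chro (3L 22878693 to 22879110), which encodes the interband protein Chromator, reached 11.3 ± 0.573 (SD, n = 3), with the start site of Ssl1 also within 500 bp. Among regulators of RNA and translation were CNBP, a zinc-knuckle nucleic acid binding protein (11.4 ± 1.52), and larp, a La-related RNA-binding protein (8.69 ± 1.01). Mitochondrial genes included PNPase, a polynucleotide phosphorylase (10.1 ± 0.856), and mRpL41, a mitochondrial ribosomal protein gene (8.49 ± 0.417). The peak assigned to Art3, an arginine methyltransferase gene (9.52 ± 0.489), also had a TSS of the mitochondrial ribosomal protein gene mRpS10 within 500 bp. The peak assigned to CenG1A (9.21 ± 0.407) likewise had a TSS of mRpS23 within 500 bp. Further promoter peaks were at px, a wing vein patterning gene (14.7 ± 1.26), bdg (15.01 ± 1.42), CG14100 (14.4 ± 1.02), Ugalt, a UDP-galactose transporter gene (13.4 ± 1.67), CG1888 (10.5 ± 1.41), the zinc finger gene Cf2 (9.65 ± 0.957) and the apoptosis inhibitor gene Diap2 (8.46 ± 0.628). Of the 25 summits, 9 had start sites of more than 1 gene within 500 bp, which also holds for CNBP (CG9849), Cf2 (CG3008), mRpL41 (lncRNA:CR44463) and Diap2 (bug).

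The 5 distal peaks of this set were as strong as many of the promoter peaks. The peak whose nearest TSS belongs to cbt, a zinc finger transcription factor gene, lay at 2L 480839 to 481314 in an intron of ush, 1397 bp from that TSS, with a relative signal of 17.1 ± 1.02 (SD, n = 3). ush encodes a zinc finger cofactor of GATA factors. The peaks at CG11050 (12.4 ± 0.863) and at Lk6 (11.4 ± 0.773), a kinase gene, lay in introns of those genes. The peak with CG13323 as nearest gene lay between genes at 2R 13035137 to 13035521, 11912 bp from the TSS, with a relative signal of 10.5 ± 0.470. The last, at 3R 16222321 to 16222686, was 916 bp from lncRNA:CR45643 and had a relative signal of 8.55 ± 0.924 (SD, n = 3).

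**Figure D1:**
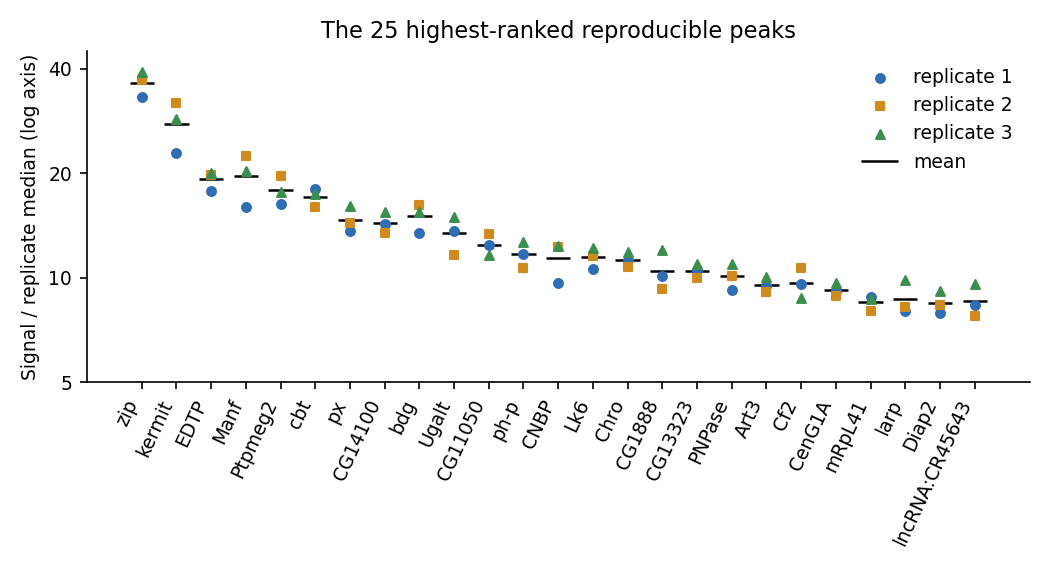
Relative signal of the 25 highest-ranked reproducible peaks, each named by the gene with the nearest TSS; the y axis is the signal divided by the median of the replicate over all reproducible peaks, on a log axis. Points are the 3 replicates and bars their mean, which runs from 36.4 at zip to 8.46 at Diap2.

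The gene of the tagged protein itself had no reproducible peak within it. CG16863 lies at 2L 13790959 to 13793264 on the forward strand. The nearest reproducible summit, at 13793672, was 408 bp past the end of the gene and 151 bp downstream of a TSS of Sec71. Its relative signal was 0.576 ± 0.156 (SD, n = 3), below the median of the reproducible peaks in each replicate. The relaxed pooled list held a weaker peak inside CG16863, with its summit at 13791434 and a signal of 39.3, against at least 108.6 for every peak in the IDR set.

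The replicates placed their strongest peaks at the same sites. Of the 3953 highest peaks of one replicate, 71.0% ± 1.12 (SD over 3 pairs) had a summit among the 3953 highest of another within 100 bp. Lists shifted at random along each arm reached 1.14% at most, and the one-sided permutation p was 0.001 for each of the 3 pairs, the smallest that 1000 shifts can give. Across reproducible peaks the Spearman correlation of signal between replicates was 0.715 ± 0.0107 (SD over 3 pairs). It is a correlation across peaks, which are not independent replicates, so no p is given. A replicate peak lay within 100 bp of 96.7% ± 0.615 of the reproducible summits (SD, n = 3). Each replicate contributed to the pooled signal that chose these summits, so this share and the correlation are not independent of that choice. The overlap of the strongest peaks compares the replicate lists alone. The overlap and the correlation depended on the distance allowed: within 50 bp the overlap was 57.8% and the correlation 0.570.

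Reproducible peaks were at promoters more often than background peaks were, and were largely absent from coding sequence. Summits within 500 bp of an annotated TSS made up 1985 of 3953 (50.2%, 95% Wilson interval 48.7 to 51.8), against 5000 of 17875 background summits (28.0%, 27.3 to 28.6). The background was every pooled relaxed summit over 1000 bp from all reproducible summits, and most of these were weak calls. The odds ratio was 2.60 (Fisher's exact test, two-sided, adjusted p = 3.9e-153 over 7 feature classes). Only 8 reproducible summits (0.202%) lay in coding exons away from promoters, against 2805 background summits (15.7%; Fisher's exact test, adjusted p = 1.2e-244). Summits in 3′ UTRs were also fewer, at 0.860% against 3.00% (Fisher's exact test, adjusted p = 3.9e-17). Introns held 34.2% of reproducible and 34.8% of background summits (Fisher's exact test, adjusted p = 0.56). The strongest 3953 peaks of the single replicates had 50.6% ± 1.30 at promoters and 0.565% ± 0.337 in coding exons (SD, n = 3). The intervals and tests count peaks as independent, although 204 neighbouring pairs of reproducible summits lay within 500 bp of each other. No control library was compared. The promoter results here and below therefore cannot separate binding of the tagged protein from signal that promoters give without it.

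**Figure D2:**
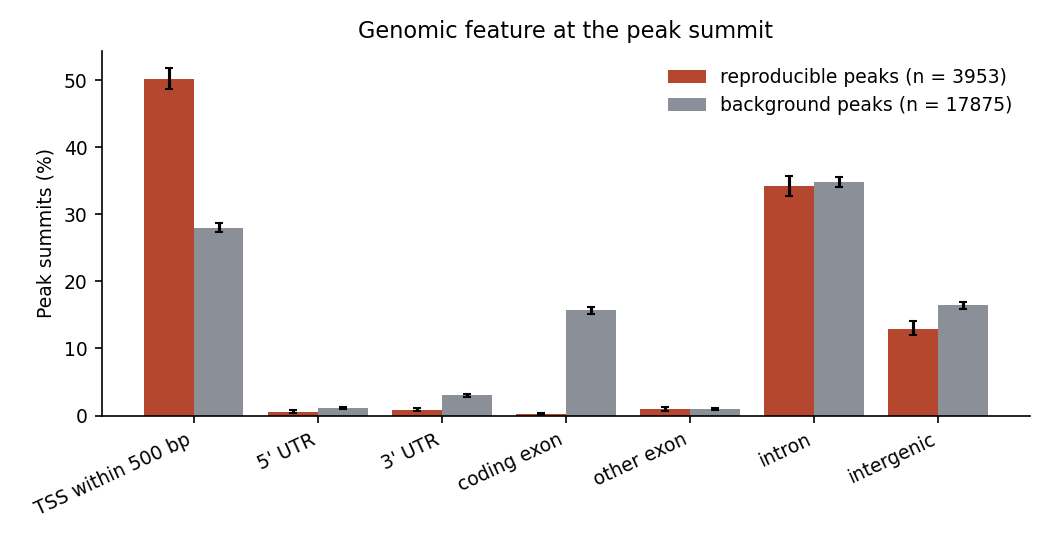
Share of peak summits (y axis, percent) in each annotated feature (x axis) for 3953 reproducible and 17875 background peaks; bars give the share and error bars its 95% Wilson interval. Promoters hold 50.2% of reproducible and 28.0% of background summits, and coding exons 0.202% and 15.7%.

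At promoters the summits sat upstream of the start site. Of the 1985 promoter summits, 1566 (78.9%) lay upstream of the nearest TSS, with a median position of -88 bp. Of the background promoter summits, 50.7% lay upstream, with a median position of -3 bp (odds ratio 3.63, Fisher's exact test, two-sided, p = 6.0e-109). Promoter peaks were slightly higher than distal ones. Their median relative signal was 1.05 ± 0.0162, against 0.953 ± 0.0125 for distal peaks (SD, n = 3), and the difference of 0.0944 ± 0.0286 was positive in 3 of 3 replicates. With a TSS window of 200 bp the difference was 0.0576, which lies outside 1 SD of the main value.

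**Figure D3:**
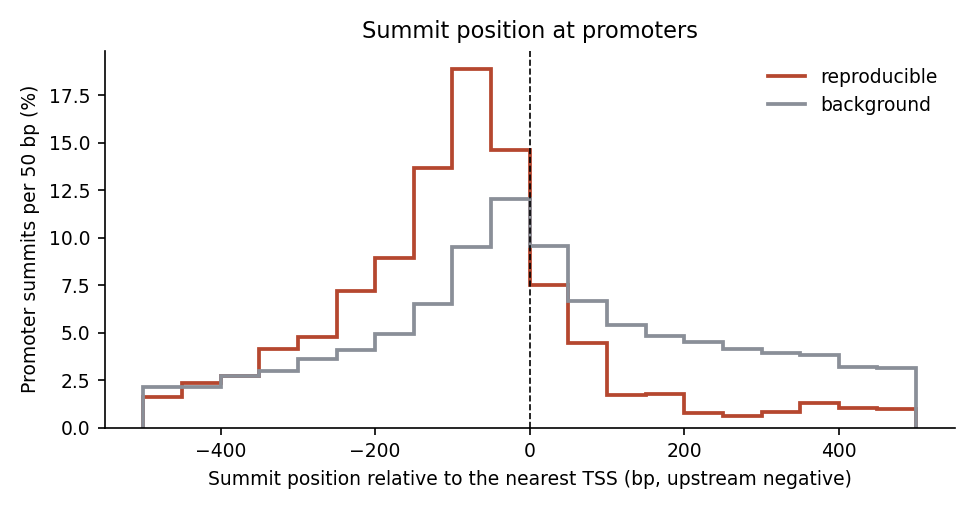
Position of promoter summits relative to the nearest TSS (x axis, bp, upstream negative) as the percent of promoter summits in each 50 bp bin (y axis). The 1985 reproducible summits peak upstream, with a median of -88 bp, whereas the 5000 background summits have a median of -3 bp.

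Bound promoters were often head to head. A gene counted as bound when a reproducible summit lay within 500 bp of one of its start sites, which held for 2592 of the 7578 genes with any pooled relaxed summit there (34.2%). Of the bound genes, 1698 (65.5%) had a start site of another gene on the other strand within 1000 bp upstream, against 2293 of 4986 unbound genes (46.0%; odds ratio 2.23, Fisher's exact test, two-sided, p = 2.6e-59). A single peak between head-to-head genes marks both as bound. With each head-to-head group counted once, an alternative chosen after seeing the data, the shares were 50.8% and 30.8% (odds ratio 2.31, Fisher's exact test, p = 5.1e-47), and a group with more start sites had more chances to be bound.

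Of the 34 gene lists fixed beforehand, 1 was bound more often than other genes, cytosolic ribosomal proteins, and 2 were bound less often. Of 85 cytosolic ribosomal protein genes with a relaxed peak at a start site, 59 were bound (69.4%, 95% Wilson interval 59.0 to 78.2), against 33.8% of all other genes (odds ratio 4.44, Fisher's exact test, two-sided, adjusted p = 1.2e-09). The highest-ranked were RpS27 (relative signal 4.62 ± 0.588), RpS28a (4.06 ± 1.14), RpL7 (3.71 ± 0.914) and RpS20 (2.89 ± 0.406; SD, n = 3 for each). The summit at RpS28a was 436 bp from its start site, whereas that at RpS27 was 13 bp and that at RpL7 was 18 bp away. Mitochondrial ribosomal protein genes were bound in 27 of 51 cases (52.9%, 39.5 to 66.0), which did not pass the threshold (Fisher's exact test, adjusted p = 0.060). Their excess of 18.9 points over other genes depended on the peak set. It passed with the strongest peaks of replicate 1 (21.9 points, Fisher's exact test, adjusted p = 0.0127). It also passed within strata of the number of start sites (permutation test, adjusted p = 0.0385), an alternative chosen after seeing the data. Against all annotated genes, with or without a relaxed peak, it passed as well (22.8 points, Fisher's exact test, adjusted p = 8.1e-06). It was 11.7 points with strong peaks found in at least 2 replicates (Fisher's exact test, adjusted p = 0.35), and 3.74 to 7.51 points with the smaller sets shared by the other replicates when 1 was left out. Their highest-ranked members were mRpS10 (9.52 ± 0.489) and mRpS23 (9.21 ± 0.407). Translation factor genes were bound in 16 of 32 cases (Fisher's exact test, adjusted p = 0.31), led by eIF6 (6.46 ± 0.0235) and eEF1gamma (2.85 ± 0.0799). Among other genes used by every cell, the bound shares were 12 of 25 for RNA polymerase II and mediator (MED30 3.18 ± 0.0299, Polr2H 3.10 ± 0.295), 5 of 23 for the spliceosome (Sf3b6 1.12 ± 0.0894, Prp31 1.07 ± 0.0810), 13 of 43 for oxidative phosphorylation (ND-MWFE 2.53 ± 0.466, ND-ASHI 2.00 ± 0.265), 8 of 26 for the proteasome (Rpn5 2.76 ± 0.512, Rpn3 1.66 ± 0.233) and 8 of 21 for tRNA synthetases (AsnRS 3.22 ± 0.560, SerRS 2.28 ± 0.423). None of these 5 lists passed the threshold (Fisher's exact test, adjusted p = 0.57, 0.58, 0.81, 0.95 and 0.95).

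tRNA genes were bound less often than other genes, and snoRNA genes were so with the main settings but not with 5 of the alternatives. Only genes with a relaxed peak at a start site were compared, 97 of 295 annotated tRNA genes and 79 of 273 snoRNA genes. Reproducible peaks lay at 9 of 97 tRNA genes (9.28%, 95% Wilson interval 4.96 to 16.7; odds ratio 0.194, Fisher's exact test, adjusted p = 2.7e-07), among them tRNA:Tyr-GTA-1-8 (relative signal 4.95 ± 0.878), tRNA:Gln-TTG-2-1 (1.51 ± 0.370), tRNA:Phe-GAA-1-2 (1.40 ± 0.171) and tRNA:Val-CAC-2-5 (1.39 ± 0.264; SD, n = 3 for each). These summits lay 236 to 487 bp from the tRNA start sites. They lay at 13 of 79 snoRNA genes (16.5%, 9.88 to 26.1; Fisher's exact test, adjusted p = 0.0057), among them snoRNA:U49:66Da (2.70 ± 0.642), snoRNA:Psi28S-2949 and snoRNA:Or-aca5, which share a peak (2.53 ± 0.227), and snoRNA:Or-CD11a (1.79 ± 0.128). Start sites of small RNAs often lie inside other genes or in clusters, so a peak can belong to a neighbour. How reads were assigned among near-identical tRNA copies is not given in the sources used here. The snoRNA share was -17.9 points from that of other genes. The difference was -22.3 points with a TSS window of 200 bp, where it did not pass (Fisher's exact test, adjusted p = 0.30), and shrank to -6.28 points with 1000 bp (Fisher's exact test, adjusted p = 0.39). It also did not pass with the strongest peaks of replicate 3 (-13.5 points, Fisher's exact test, adjusted p = 0.084) or with peaks at or above the median signal (-9.42 points, adjusted p = 0.37). Within strata of the number of start sites, an alternative chosen after seeing the data, its adjusted p was 0.063 (permutation test).

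**Figure D4:**
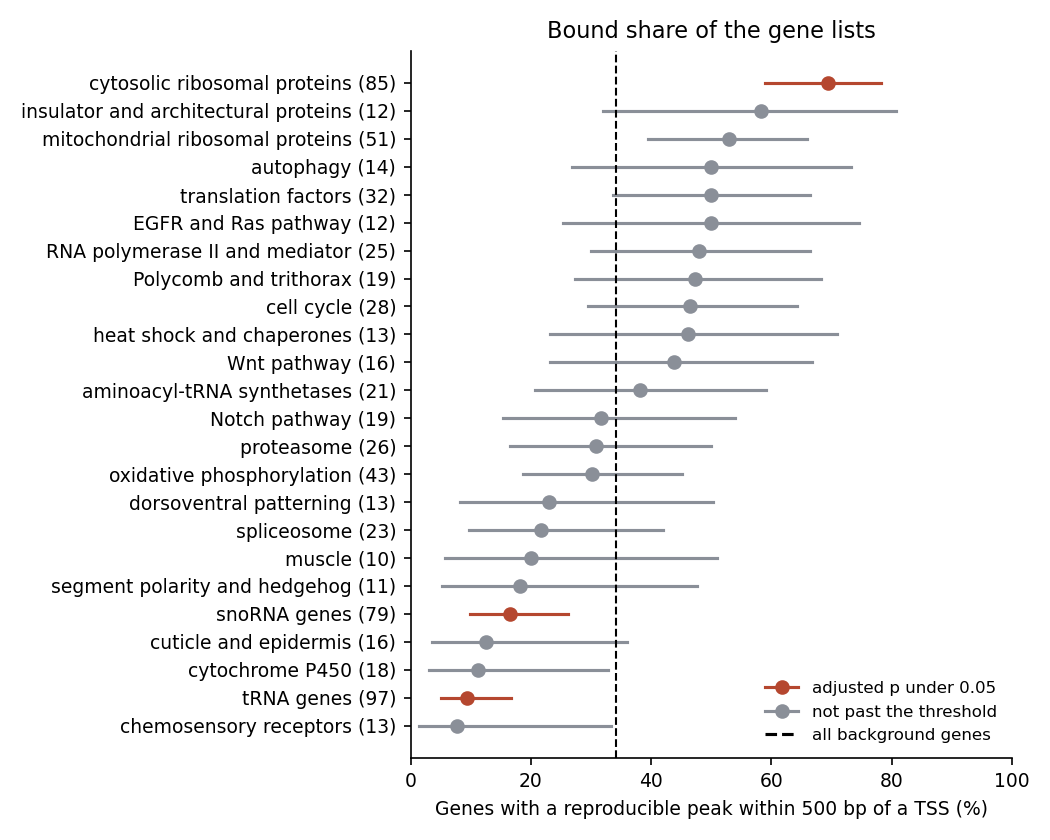
Percent of genes with a reproducible peak within 500 bp of a TSS (x axis) for each list with at least 10 background genes, their number in parentheses; bars are 95% Wilson intervals and the dashed line is the 34.2% of all background genes. Cytosolic ribosomal proteins lie above the line at 69.4%, and tRNA and snoRNA genes below it at 9.28% and 16.5%.

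With the main background, no list of embryonic patterning or signalling genes passed the threshold, and most of these lists were too small for a firm statement. Against all annotated genes, which include genes without any relaxed peak, the Wnt pathway and the EGFR and Ras pathway lists passed. So did the Polycomb and trithorax, the insulator and architectural protein, and the cell cycle lists. None of the 6 Hox genes with a relaxed promoter peak was bound at a promoter (95% Wilson interval up to 39.0%; Fisher's exact test, adjusted p = 0.38). Hox gene bodies held 9 of 1968 distal reproducible summits (0.457%), against 36 of 12875 distal background summits (0.280%; Fisher's exact test, adjusted p = 0.91). In the gap and maternal list 1 of 6 was bound, bcd, the anterior determinant (relative signal 1.45 ± 0.0689). Segment polarity genes had 2 of 11, smo, a transducer of Hedgehog signals (3.32 ± 0.202), and nkd, a Wnt antagonist (1.37 ± 0.250). Notch pathway genes had 6 of 19, with the bHLH repressor genes E(spl)m3-HLH (2.51 ± 0.784) and E(spl)m7-HLH (1.28 ± 0.131) ranked first. Wnt pathway genes had 7 of 16, with the kinase gene sgg (3.89 ± 0.467) and Axn (2.22 ± 1.38). EGFR and Ras pathway genes had 6 of 12, with the ligand gene spi (3.28 ± 0.337) and Ras85D (1.41 ± 0.257). JAK/STAT pathway genes had 3 of 4, with Stat92E (1.14 ± 0.240) and the receptor gene dome (0.893 ± 0.277). Polycomb and trithorax genes had 9 of 19, with ph-p (11.7 ± 1.02) and Trl, which encodes GAGA factor (1.81 ± 0.422). Insulator and architectural protein genes had 7 of 12, with Chro (11.3 ± 0.573) and Cp190 (2.41 ± 0.755). Cell cycle genes had 13 of 28, with Dp (2.52 ± 0.418) and dpa (1.72 ± 0.259). Tissue genes such as elav, a neuronal RNA-binding protein gene (3.68 ± 0.667), sls, a titin-like muscle gene (2.93 ± 0.312), and fkh, a forkhead factor gene of gut and salivary gland (2.80 ± 0.343; SD, n = 3 for each), were also bound. Their lists had 3 of 8 (nervous system), 2 of 10 (muscle) and 3 of 9 (trachea, gut and salivary gland) genes bound. With the main background, adjusted p was at or above 0.38 for all of these lists (Fisher's exact test). Among genes with a relaxed promoter peak, cytochrome P450 genes (2 of 18, with 87 annotated) and chemosensory receptor genes (1 of 13, with 186 annotated) had low shares. These lists did not pass the threshold (Fisher's exact test, adjusted p = 0.26 for each), but both passed against all annotated genes.

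Among the sequences at the summits, the CTCF consensus was the most enriched of 30 fixed motifs. AGRKGGCGC, a consensus of the insulator protein CTCF, was within 50 bp of 68 of 3906 reproducible summits (1.74%, 95% Wilson interval 1.38 to 2.20), against 16 of 3906 background summits matched on TSS class and GC (0.410%; odds ratio 4.31, Fisher's exact test, two-sided, adjusted p = 2.2e-07). It passed in each of 100 other random draws of the matched background, with odds ratios from 2.37 to 5.75. The Runt consensus AACCGCAA was rarer, at 4 against 20 summits (Fisher's exact test, adjusted p = 0.023), but it passed in only 18 of the 100 other draws. The 28 other motifs did not pass, among them the GAGA element (60 against 49 summits) and the DRE, the target of the promoter factor DREF (89 against 67 summits; Fisher's exact test, adjusted p = 0.33). Most reproducible summits therefore carried no match to the enriched consensus.

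A search over 13839 8-mers, ranked on arms 2L, 3L and X and tested on 2R, 3R and 4, gave 3 of the 10 ranked 8-mers past the threshold. CACTGTGC was at 26 of 1647 held-out reproducible summits, against 7 of 1657 background summits (Fisher's exact test, adjusted p = 0.0075). CACAGTGG was at 26 against 10 (Fisher's exact test, adjusted p = 0.024), and its first 7 bases are also in the reverse complement of CACTGTGC, GCACAGTG. GATGGCGC was at 18 against 4 (Fisher's exact test, adjusted p = 0.012), and it is part of the CTCF consensus. In 20 other draws of the background, CACTGTGC and CACAGTGG each passed in 13 and GATGGCGC in 11. The 7 that did not pass were CACTGACG, ATAGCCAT, AGAATTAC, AACAAGTG, GACCACAA, AAGAGAAT and GTGGCACA. In the discovery arms no 8-mer passed after adjustment over all that were ranked (Fisher's exact test, smallest adjusted p = 0.096).

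The summits themselves were AT-rich. GC content within 50 bp of the reproducible summits averaged 36.1%, against 42.9% in windows centred 200 bp to either side, whereas background summits had 44.8% and 44.6%. For the strongest 3953 peaks of the single replicates the values were 36.7% ± 1.21 at the summit and 42.9% ± 0.107 beside it (SD, n = 3). The 500 strongest reproducible peaks had 33.7% at the summit and 44.7% beside it.

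**Figure D5:**
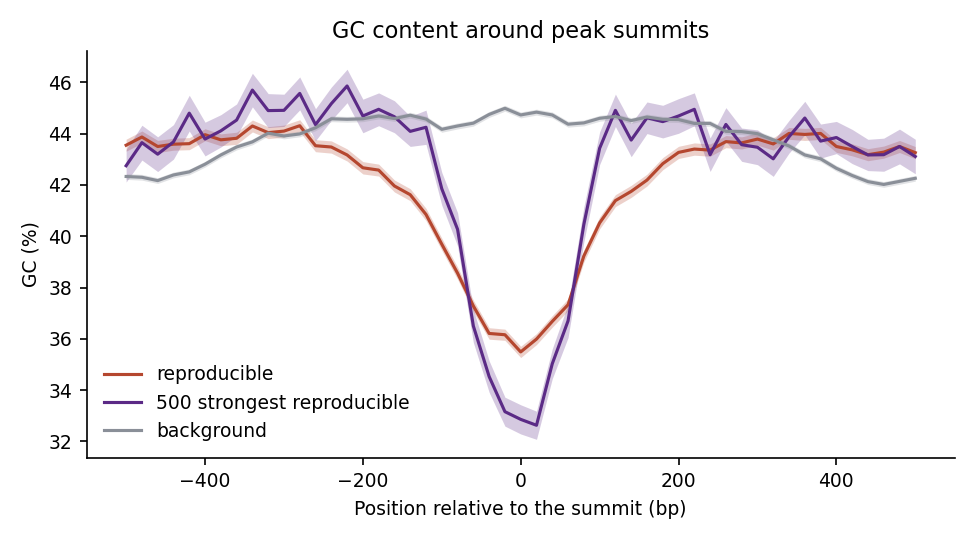
Mean GC content (y axis, percent) in 21-bp windows by position relative to the summit (x axis, bp) for reproducible, the 500 strongest reproducible and background peaks; shading is ± 1 standard error over peaks. GC falls to 35.5% at reproducible summits and 32.9% at the 500 strongest, and stays at 44.7% at background summits.

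By chromosome arm, the X held more and chromosome 4 fewer of the reproducible peaks than of the background. The X had 750 of 3953 (19.0%, 95% Wilson interval 17.8 to 20.2) against 15.5% of background summits (odds ratio 1.27, Fisher's exact test, two-sided, adjusted p = 8.7e-07 over 6 arms). The strongest 3953 peaks of the single replicates had 18.9% ± 0.418 on the X (SD, n = 3). Chromosome 4 had 13 (0.329%) against 0.817% (odds ratio 0.401, Fisher's exact test, adjusted p = 0.0017). The other 4 arms did not pass, with adjusted p of 0.11 or more (Fisher's exact test). Against arm length in place of the background peaks, the X no longer passed (exact binomial test, adjusted p = 0.064), at 31.9 reproducible peaks per Mb against 28.1 to 31.2 on the large autosome arms. With peaks at or above the median signal, chromosome 4 no longer passed (Fisher's exact test, adjusted p = 0.49).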

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

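The dm3 relaxed lists held peaks on sequences that none of the comparisons used. In the pooled list 35 peaks (0.166%) lay on heterochromatic or unplaced sequences, 8 of them on Uextra and 8 on 3LHet, with a highest signal of 105.2. The relaxed lists of replicates 1, 2 and 3 held 74, 43 and 50 such peaks, and the dm3 IDR set held 0. The dm6 lists used here held peaks on the 6 main arms alone. No biological explanation was tested.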

How the results depend on the processing

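The promoter excess passed in all 12 alternatives and the excess of head-to-head promoters in all 4. Settings with background draws, start-site strata, head-to-head groups or 1 peak per 500 bp were chosen after seeing the data. The cause was not tested for the changes below, unless stated.

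The reproducible set had 3859 peaks in dm3, and 1977 with signal at or above the median, by construction. The correlation between replicates was 0.570 at 50 bp, 0.777 at 250 bp and 0.757 without the summits lacking a replicate peak, and 0.706 to 0.727 with a replicate left out. The overlap of the strongest peaks was 81.7% for the top 1000, 58.0% for 2 times the peak count, 78.5% with 1 bp of overlap and 57.8% at 50 bp, and 70.0% to 72.2% with a replicate left out. The number of arms past the threshold was 2, but 1 with signal at or above the median (chromosome 4 lost) and 1 against arm length (X lost). With a replicate left out, promoter shares were 50.7% to 52.4% and the promoter minus distal signal was 0.0815 to 0.110. A TSS window of 200 bp gave 0.0576 for the latter.

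The 3 gene list calls became 16 against all annotated genes, a background that includes genes without any relaxed peak, 4 with the peaks of replicate 1 (mitochondrial ribosomal proteins added, Fisher's exact test, adjusted p = 0.0127), 2 with a window of 200 or 1000 bp, the peaks of replicate 3 or signal at or above the median (snoRNA genes lost in each), and 1 for protein-coding genes, where tRNA and snoRNA genes are absent by construction. With a replicate left out the count was 3 to 3, on the same lists. Within strata of the number of start sites, 3 lists passed, 2 of them among the main calls: mitochondrial ribosomal proteins passed (permutation test, adjusted p = 0.0385) and snoRNA genes did not (adjusted p = 0.0629). The excess of mitochondrial ribosomal proteins was not stable: it was 18.9 points with the IDR set, 11.7 with strong peaks in at least 2 replicates (3636 peaks; Fisher's exact test, adjusted p = 0.35) and 3.74 to 7.51 with a replicate left out (adjusted p = 0.73 to 0.97). The last also replaces the IDR set by 2766 to 2854 shared peaks, so the drop cannot be put down to the replicate left out. Lists close to the general level changed sign without a call. Oxidative phosphorylation was 0.215 points above other genes with a window of 200 bp, 1.99 against all genes, 1.49 with signal at or above the median, 1.76 in replicate 1 and -2.45 to 2.04 with a replicate left out. The proteasome was 2.40 points above against all genes, 1.49 in replicate 1 and -10.5 to 1.05 with a replicate left out. For tRNA synthetases the difference was -4.56 points in replicate 2 and -6.85 to 7.46 with a replicate left out.

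The 2 motif calls became 1 with windows of 100 bp to each side of the summit in place of 50 bp, 15 against flanking windows and 12 without GC matching (the AT-rich summits then differ in GC from their background), 4 with the peaks of replicate 3, and 1 as the median of 100 other background draws. The count stayed at 2 with signal at or above the median and with the peaks of replicates 1 and 2. Runt was lost in each (Fisher's exact test, adjusted p = 0.73, 0.58 and 0.86). Initiator, TATA box and E-box CAGCTG passed instead, and a call can lie in either direction. In the 100 other draws with the main peaks, odds ratios were below 1 for Initiator (0.764 to 0.925) and the TATA box (0.654 to 0.963). These motifs were thus rarer at the reproducible summits. For E-box CAGCTG the odds ratios were 0.970 to 1.53. CTCF passed in all of the settings above. The DRE and the CGATA core were among the added calls against flanking windows, without GC matching and with the peaks of replicate 3. In the 100 other background draws, odds ratios were 1.16 to 1.63 for the DRE and 1.07 to 1.24 for the CGATA core. They passed in 0 and 6 of those draws. The 3 8-mers became 6 with 100 bp to each side (CACTGTGC and CACAGTGG among them, GATGGCGC not) and 9 against flanking windows (none of the 3 among them). With discovery and test arms exchanged 3 passed, of which CACTGTGC alone was among the main 3. Some of the added 8-mers held CACTG on 1 strand, as CACTGTGC and CACAGTGG do. These were TACAGTGA, TACACTGA and CACTGTAC with 100 bp to each side, and CAACACTG against flanking windows and with arms exchanged. The other added 8-mers did not hold it. This likeness was seen after the results and was not tested. Read depth is unknown, so its effect on weak peaks could not be measured.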

Other observations

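The tests on the density of the X and on housekeeping genes, the start-site content test on the X, and the background draws were chosen only after the results were seen. The strata of start sites were chosen after the main list results were seen, but before their own result was. The genes in the next paragraph were chosen after the results were seen, as those with the most reproducible summits.

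Some long genes held many reproducible peaks. The lncRNA gene lncRNA:CR44357 (X 7166451 to 7405797) held 19 reproducible summits, and the overlapping CG1677 held 16. The cell adhesion gene kirre (X, 394.1 kb) held 16, ush 14, Raf, a kinase gene of the receptor tyrosine kinase pathway, 12, and shn, a zinc finger gene of Dpp signalling, 11. Counts were not adjusted for gene length or tested, and long genes hold more peaks by chance. The CTCF consensus was found at 6 of 791 reproducible peaks in the lowest quintile of signal, 19 of 791 in the middle quintile and 14 of 791 in the highest, which was not tested.

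A hypothesis was that distal peaks in gene bodies favour some of the fixed lists. With distal reproducible summits compared with distal background summits, 0 of 34 lists passed (Fisher's exact test), and the smallest p-values were those of Polycomb and trithorax genes (11 of 1968 distal reproducible summits, 0.559%, against 29 of 12875, 0.225%; odds ratio 2.49, Fisher's exact test, p = 0.016, adjusted p = 0.34) and JAK/STAT genes (10 against 25 of the same totals; odds ratio 2.625, Fisher's exact test, p = 0.020, adjusted p = 0.34). Both lay in the direction of the hypothesis, but after adjustment no list supported it. Another was that the CTCF consensus sits at the summit itself. It was within 50 bp of 68 of 3953 summits and of 23 of 7906 points 300 bp away (odds ratio 6.00, Fisher's exact test, p = 7.0e-16), in line with a position at the summit. The windows and points are those of the alternative with flanking windows given above, so this is not separate support for the enrichment. The consensus was at 28 promoter and 40 distal summits.

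The AT-rich core at the reproducible summits was weighed against position and GC bias. Upstream promoter DNA cannot be the whole cause, since summits over 500 bp from every TSS had a core GC -8.93 points from their flanks (SE 0.264), and -8.08 ± 0.977 in the replicates' strongest distal peaks (SD, n = 3). A difference in GC over the whole window out to 200 bp on each side cannot be the whole cause either. With background summits matched on the GC of that window, core included, core GC still differed by -3.29 points (SE 0.202). Since that window holds the core, the matching itself removes part of the difference. Selected fragments were 200 to 800 bp, so a GC bias of fragments shorter or longer than that window was not excluded. Neither comparison took coding sequence into account, in which reproducible summits were rarer than background summits. An AT-rich sequence preference may remain, as may bias in the reads or in the caller that acts on shorter stretches. No biological explanation was tested.

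The excess of reproducible peaks on the X lay in distal summits, where the X held 21.7% of reproducible and 15.5% of background summits (odds ratio 1.51, Fisher's exact test, p = 2.5e-11). The Fisher test counts summits as independent, although many lay in single genes of the X, such as lncRNA:CR44357 (19 summits), kirre (16) and Raf (12). Some autosomal genes also held many, such as ush (14) and shn (11). At promoters the shares were 16.3% and 15.6% (odds ratio 1.06, Fisher's exact test, p = 0.47), so start-site content cannot be the whole cause. Background peaks were sparser on the X, at 0.860 times their density on the large autosome arms (95% block bootstrap interval 0.732 to 0.990), and a lower copy number of the X in males could contribute to that, which was not tested. The density of reproducible peaks on the X was 1.09 times that on these arms, with an interval of 0.884 to 1.31. That interval holds 1, expected if fewer weak peaks were the whole cause. It also holds 1.27, the ratio of reproducible to background density. Resampled in blocks of 1 Mb, which keeps neighbouring summits together, that ratio had an interval of 1.12 to 1.41. The excess over background was 1.44 times as large at distal as at promoter summits (1.21 to 1.72). Other block sizes were not tried for either ratio. For distal reproducible peaks the density was 1.29 times that on these arms. Its interval lay above 1 with blocks of 0.5 Mb (1.05 to 1.57) and 1 Mb (1.007 to 1.60). The interval included 1 with blocks of 2 Mb (0.914 to 1.67) and 5 Mb (0.779 to 1.75). For promoter peaks the density ratio was 0.908 (0.723 to 1.11 with blocks of 1 Mb). Whether the X holds more reproducible peaks, or only fewer weak ones to compare them with, therefore stays open, also at distal sites, and no biological explanation was tested.

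The excess at ribosomal protein promoters was weighed against gene structure and general housekeeping binding. It kept a permutation p of 0.0002 within strata of the number of start sites, the smallest 10000 draws can give two-sided, with 59 bound and 30.4 expected. The 7 other fixed lists of genes used by every cell were together bound in 40.3% of cases (89 of 221, 95% Wilson interval 34.0 to 46.8), against 33.6% of the remaining genes (Fisher's exact test, p = 0.043). Without mitochondrial ribosomal proteins the share was 36.5% (62 of 170; Fisher's exact test, p = 0.46), and their own excess changed with the peak set, as given above. Shares were also 50% for translation factors and 48% for RNA polymerase II and mediator. They were 38.1% for tRNA synthetases and 21.7% to 30.8% for the other lists. Leaving out another list was not tried, so the pooled excess cannot be put down to 1 list. The 8 lists, cytosolic ribosomal proteins included, did not share 1 level of binding. With bound status permuted over their 306 genes, no draw gave any list as small a Fisher p against the others as that of cytosolic ribosomal proteins (permutation p = 1.0e-04, the smallest that 10000 draws can give), so binding of housekeeping promoters at a common share is not the whole cause. The permutation takes into account that this list was singled out, but not start sites shared between genes. Transcription level, which is high for ribosomal protein genes, may still contribute, since no expression data were analysed here. A preference of the tagged protein for these promoters remains a hypothesis.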
